A study of Mus musculus with 12 samples.

How the data were processed

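RNA from mouse embryonic fibroblasts was measured on 12 Affymetrix expression arrays, 2 for each of 6 groups: DMSO (the vehicle), IFNa, IFNg, AMN107, AMN107-IFNa and AMN107-IFNg. AMN107 is nilotinib, an inhibitor of the ABL kinases. Per the labels, cells were given AMN107 or not and then interferon or not for 6 h. The labels give no dose or duration for AMN107 and call the arrays of a group biological replicates.

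The deposited values are linear probe set signals (intensity); the processing notes name MAS5 without a version, a setting or a scaling rule. The 2% trimmed mean of the arrays ran from 100.4 to 113.5, so the arrays had not all been set to 1 trimmed mean. It was 100.4 and 101.2 on the DMSO arrays, 106.2 and 104.9 on the IFNg arrays and 107.9 and 113.5 on the IFNa arrays. On the 6 AMN107 arrays it was 108.4 to 110.8. The table held 45101 probe sets. After 64 control probe sets were left out, 34945 carried exactly 1 gene in the platform annotation, 932 several and 9160 none. Symbols of 34741 were looked up by gene ID in a RefSeq table of assembly GRCm38.p6, used for names only, and 0 changed; 204 kept the annotation's symbol.

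Signals were taken as log2(signal + 8.66), where 8.66 is the mean over the 12 arrays of the 25th percentile. A probe set was tested if its signal lay above the array's median on at least 2 of 12 arrays (24363 probe sets, 21249 with 1 gene). Of several probe sets for a gene, the one with the highest mean log2 value was used, which left 12192 genes. No further normalization was applied.

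A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend). Each of 11 contrasts was tested two-sided, and p was adjusted by Benjamini-Hochberg over the 12192 genes with a threshold of 0.05. The contrasts were the responses to IFNa and to IFNg without and with AMN107, the effect of AMN107 without interferon, with IFNa and with IFNg, its average over these 3 states, the interaction of AMN107 with each interferon, and IFNg against IFNa. SE is the standard error of limma's log2 difference. Folds are 2 to the power of this difference, so they are ratios of signal + 8.66 and lie below ratios of signal for dim genes. The limma p-values rest on a spread per gene that all 6 groups share, estimated from the 2 arrays of each group. The IFNa arrays widen this shared spread (replicate difference SD 0.401 against 0.119 to 0.144 in the other groups). Tests that use the IFNa arrays can therefore call too many genes, and the other tests too few. The number of arrays limits the precision. The labels do not say that replicate numbers link arrays of different groups. Over 15 pairs of groups the correlation of the arrays' deviations ran from -0.143 to 0.312, above 0.1 in 4 and below -0.1 in 3. The 3 pairs among IFNa, AMN107 and AMN107-IFNa gave 0.204, 0.217 and 0.312, so a shared factor in these groups is not ruled out. No pairing was used in the comparisons, and the replicate number was tried as a block.

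To compare interferon responses with and without AMN107, induced genes were those with adjusted p under 0.05 and a log2 rise of at least 1 in the mean of both responses. The mean is independent of the difference only if the groups vary alike. The IFNa arrays varied more (replicate difference SD 0.401 against 0.119 to 0.144), so for IFNa this choice favours genes with a more negative difference. The median interaction over these genes was tested with fry, which asks whether the genes of a set move, on balance, one way, with its p adjusted over the 2 interferons.

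There were 27 gene lists, 7 of them markers of cell types: antiviral effectors, RNA and DNA sensors, interferon-inducible GTPases, MHC class I presentation, MHC class II presentation, interferon signalling, interferon feedback inhibitors, chemokines and cytokines, NF-kappaB targets, cell death and checkpoint ligands, ABL and other nilotinib targets, cell cycle and DNA replication, p53 targets, immediate early and SRF targets, extracellular matrix, cholesterol and fatty acid synthesis, lysosome and autophagy, ER stress and amino acid response, oxidative and xenobiotic stress, hypoxia and glycolysis, and the markers of fibroblasts, macrophages and leukocytes, endothelium, epithelium, muscle, fat and cartilage, and neurons. Lists were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again at an estimated correlation, with adjustment over the 27 lists. List members were also adjusted over the list alone. Only tested members were counted: 31 of 37 antiviral effectors, 8 of 16 GTPases and 13 of 20 in MHC class I, for example. A member that was dim without interferon could pass the filter through the arrays on which it was induced.

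Genes were named by a rule. Per contrast it took the 12 largest rises and 6 largest falls with an adjusted p under 0.05 whose arrays all lay beyond those of the other group (a condition not used for interactions), up to 4 members per list with the largest called change, filled up to 2, and fixed genes: Stat2, Irf1, Irf7 and Irf9 for interferon contrasts and Abl1, Abl2, Pdgfra and Pdgfrb for AMN107 contrasts. The comparisons, tests, lists, naming rule and settings to vary were written before the data were examined.

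The settings varied were quantile normalization, median centring, no pseudocount (signal floored at 1), a pseudocount at the 50th percentile (21.6), no filter, a filter at the 75th percentile, every probe set on its own, eBayes without a trend, a fit on only the groups compared, the replicate number as a block, a 2-fold minimum, a 4-fold minimum for induced genes, and leaving out each of the 12 arrays in turn. With an array left out, the lone array of its group was assumed to vary like the other groups. After seeing the data, array weights, a fit without both IFNa arrays and the removal of each array's trend on 5' signal loss were added.

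The procedure was tested on simulated data with 12192 genes. For AMN107 without interferon it recovered 59.7% of genes changed 1.5-fold, 91% of those changed 2-fold and 100% of those changed 4-fold, and 6.7% of its calls were false. For the interaction of AMN107 with IFNg it recovered 20.9%, 83.6% and 95.5%, with 8.9% false calls. Neither the response to IFNa nor the interaction of AMN107 with IFNa was assessed on simulated data. These rates hold for the simulated data only and are not error rates of the tests on the real arrays. There the IFNa arrays varied more (replicate difference SD 0.401 against 0.119 to 0.144 in the other groups). Probe sets with no gene or several were left out of the named results because no single gene could be given.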

Results

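The 12 arrays had median probe set signals of 20.6 to 22.7, and the first principal component (45.7% of the variance) placed the 6 AMN107 arrays apart from the 6 arrays without it. The arrays of a group correlated at 0.997 to 0.998 across genes, except the IFNa arrays at 0.976. IFNa replicate 2 had a 5'/3' signal ratio of 0.0252 for GAPDH and of 0.212 for actin. On the other 11 arrays the GAPDH ratio was 1.12 to 1.16 with AMN107 and 1.074 to 1.098 without. Its difference from replicate 1 had a standard deviation of 0.401 (log2), against 0.119 to 0.144 within the other groups. The LysX poly-A spike, RNA added before labelling, gave 59.6 and 66.2 on the DMSO arrays, 81.1 and 45.4 on the IFNa arrays, and 36.1 to 41.4 on all IFNg and AMN107 arrays. The BioB hybridization control gave 134.1 and 140.5 on the IFNg arrays and 171.7 and 178.9 on the AMN107-IFNg arrays, while its ranges overlapped between the AMN107 and DMSO arrays.

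**Figure D1:**
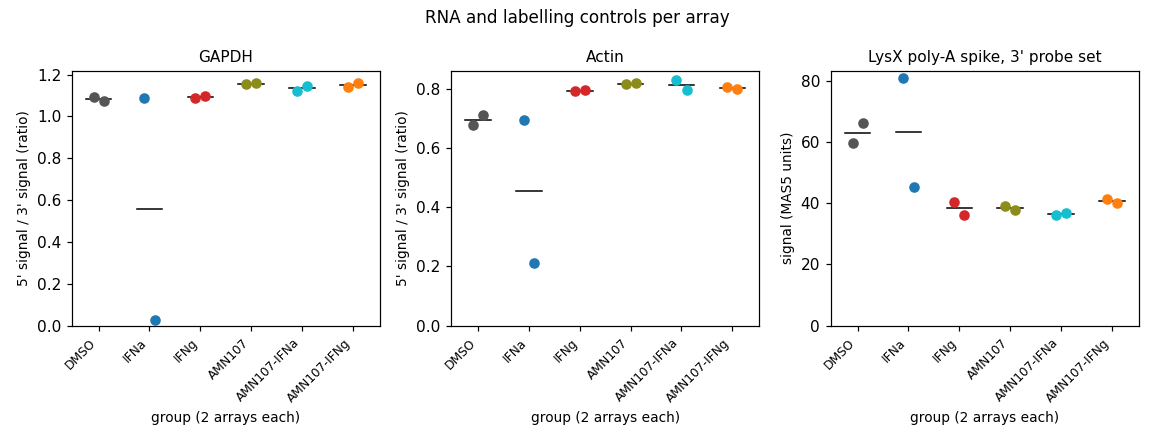
RNA and labelling controls per array: the ratio of 5' to 3' signal for GAPDH and actin, and the LysX spike signal in MAS5 units, by group, with points for the 2 arrays and lines for their mean. IFNa replicate 2 lies at 0.0252 for GAPDH, and the spike lies above 59 only on the DMSO arrays and IFNa replicate 1.

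The IFNa arrays, after 6 h of this type I interferon, were compared with the DMSO arrays. Gbp2, a GTPase of host defence, rose 18.2-fold (folds are ratios of signal + 8.66), from a signal of 23.1 ± 0.80 to 569.8 ± 20.3 (SD, n = 2; log2 4.19, SE 0.14, limma adjusted p = 2.36e-07). Usp18, which removes ISG15 from proteins and dampens type I interferon receptor signalling, rose 13-fold (log2 3.70, SE 0.23, adjusted p = 5.83e-06). Trim30a rose by 3.51. Mndal, a DNA-binding sensor family member, rose by 3.37 and Parp12 by 3.02 (log2; SE 0.15 to 0.16). Of the 31 antiviral effectors, 24 rose, 25 when adjusted over the list alone, where 1 fell, with a median log2 of 1.19. Oasl2 rose by 2.96, Ifit3, which binds viral RNA complexes, by 2.91 and Xaf1 by 2.55.

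All 8 tested interferon-inducible GTPases rose with IFNa (8 adjusted over the list alone, median 2.11), among them Gbp3 by 3.35, Gbp7 by 3.21 and Igtp by 2.19. MHC class I presentation had 12 of 13 members higher (12 over the list alone, median 0.86), with the peptide transporter Tap1 up by 1.52. RNA and DNA sensors had 9 of 13 higher (11 over the list alone, median 1.04), with Dhx58 up by 2.19 (another, dimmer probe set 0.25). In camera these lists gave adjusted p of 7.7e-17 for antiviral effectors, 1.16e-11 for GTPases, 4.64e-09 for MHC class I and 5.56e-08 for sensors. Their adjusted p = 0.102, 0.103, 0.165 and 0.103 with an estimated correlation, in the same order. Irf9, a subunit of the type I interferon transcription complex, rose by 1.44 (SE 0.17, adjusted p = 0.00102, and 0.207 in a fit of these 2 groups alone), while Stat2 gave 0.40 (SE 0.15, adjusted p = 0.0745). Irf7 gave 1.398 (SE 0.24, adjusted p = 0.0108), a call lost without DMSO replicate 1 (adjusted p = 0.108) or DMSO replicate 2 (0.06).

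The 77 genes past the test with at least a 2-fold response to IFNa were all higher. Without IFNa replicate 1, which leaves the array with 5' signal loss alone in its group, 566 passed (420 higher and 146 lower). Among all changes limma called 2140 genes (1567 higher and 573 lower), a split of 466 and 581 with quantile normalization and of 2963 and 328 with median centring. That total was 100 without DMSO replicate 1, 175 without DMSO replicate 2, 906 without IFNa replicate 2 (772 higher and 134 lower), 7142 without IFNa replicate 1 (4191 and 2951), and 464 to 728 without any 1 of the other 8 arrays. It was 35 in a fit of the IFNa and DMSO arrays alone and 84 with array weights.

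The IFNg arrays, after 6 h of the type II interferon, were compared with the DMSO arrays. Iigp1, an immunity-related GTPase, went from 10.9 ± 1.58, under the array medians, to 2691 ± 29.8 (SD, n = 2; log2 7.11, SE 0.11, limma adjusted p = 9.61e-11). The size of this rise depends on the added signal, 6.38 with the larger pseudocount and 7.96 with none. Gbp2 rose by 6.16, Ifi47 by 5.57, Gbp7 by 5.25 and Igtp by 5.22, and all 8 interferon-inducible GTPases were higher (8 adjusted over the list alone, median 4.88). Cxcl9, a chemokine for T cells, also under the array medians with DMSO, rose by 3.85 (SE 0.13, adjusted p = 1.57e-08). Of the 19 chemokines and cytokines 10 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.39), with Cxcl11 up by 3.08 (another, dimmer probe set 1.37) and Il15 by 1.53. Irf1, a transcription factor of the IFNg response, rose by 2.89, Irf8 by 3.01 (another, dimmer probe set 1.86), Batf2 by 2.50, Stat2 by 1.39 and Irf9 by 1.32. In total 9 of 17 members of interferon signalling rose (11 over the list alone, median 0.56). Irf7 gave 1.31 (SE 0.24, adjusted p = 0.00764), a call lost without DMSO replicate 1 (adjusted p = 0.0873) or IFNg replicate 1 (0.0778).

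MHC class I presentation rose in 12 of 13 members with IFNg (12 adjusted over the list alone, median 1.27), with the immunoproteasome subunit Psmb9 up by 3.23, the MHC class I activator Nlrc5 by 2.89 and Tap1 by 2.83. Antiviral effectors rose in 21 of 31 (22 over the list alone, median 1.03), led by Parp14 at 3.37 (another, dimmer probe set 0.73), and sensors in 8 of 13 (8, median 0.73). Cell death and checkpoint ligands rose in 7 of 14 (10, median 0.43), with Casp12 up by 2.60 and the checkpoint ligand Cd274 by 1.93. Camera gave adjusted p of 8.69e-29 for GTPases, 1.66e-22 for MHC class I, 3.45e-21 for antiviral effectors, 3.96e-12 for signalling, 1.46e-11 for chemokines, 1.01e-09 for cell death and 8.02e-08 for sensors. These 7 calls held with an estimated correlation (adjusted p = 0.0409 for sensors and 0.0131 for the other 6). Socs1 and Socs3, feedback inhibitors of cytokine receptors, rose by 1.52 and 1.43. Tubb3, a neuronal tubulin, rose by 3.26 (SE 0.12), and the lipid droplet gene Bscl2 and the plasminogen activator Plat fell by 0.84 and 0.80 (another, dimmer Bscl2 probe set -0.35).

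The 156 genes past the test with at least a 2-fold response to IFNg were all higher, and leaving out any 1 array gave 127 to 157, with 1 lower without IFNg replicate 2. Among all changes 1103 genes passed (746 higher and 357 lower), 689 and 899 with quantile normalization. The total was 275 and 453 without DMSO replicates 1 and 2, 324 and 433 without IFNg replicates 1 and 2, 734 without either AMN107 array, 3727 and 3733 without IFNa replicates 1 and 2, and 3728 without both IFNa arrays (1971 higher and 1757 lower). The LysX spike separated the IFNg from the DMSO arrays.

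Set directly against IFNa, IFNg gave higher signals for all 8 GTPases (8 adjusted over the list alone, median 2.38), with Iigp1 higher by 6.51 (SE 0.11, limma adjusted p = 2.42e-10) and Igtp by 3.03. Cxcl9 was higher by 4.13, Tubb3 by 3.11, Irf8 by 2.86 (another, dimmer probe set 2.002), Irf1 by 2.47, Psmb9 by 2.27, Casp12 by 2.08 and Cd274 by 1.88. In the other direction Ifih1, a sensor of double-stranded RNA, was lower by IFNg (log2 -1.19, SE 0.08, adjusted p = 1.19e-05), and Usp18 gave -1.33 (adjusted p = 0.0064; 0.0617 without IFNg replicate 2). Antiviral effectors held 10 members lower and 3 higher of 31 (12 and 3 over the list alone), and camera gave an adjusted p of 0.285 for them. MHC class I held 8 of 13 higher (9 over the list alone), chemokines and cytokines 9 of 19 with 1 lower (10 and 1). Camera gave adjusted p of 3.64e-18 for GTPases, 1.05e-08 for MHC class I and 6.87e-07 for chemokines. With an estimated correlation these were adjusted p = 0.0522, 0.137 and 0.0691.

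At least a 2-fold difference between the interferons passed for 86 genes (72 higher with IFNg and 14 lower), 381 without IFNa replicate 1 and 36 genes of any size in a fit of these 2 groups alone. Among all changes 2189 genes passed (568 higher and 1621 lower), 558 and 822 with quantile normalization. The total was 6371 without IFNa replicate 1 (2334 higher and 4037 lower), 530 and 254 without IFNg replicates 1 and 2 (the latter 122 and 132), 1270 and 1269 without AMN107 replicates 1 and 2, 1361 and 1360 without AMN107-IFNg replicates 1 and 2, and 110 with array weights.

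Between the AMN107 and DMSO arrays, from cells given no interferon, many interferon-induced genes were higher with AMN107. Usp18 rose 12.8-fold, from 78.5 ± 14.0 to 1109 ± 173 (SD, n = 2; log2 3.68, SE 0.23, limma adjusted p = 3.77e-06). Ifit3 rose 9.99-fold (log2 3.32, SE 0.15, adjusted p = 4.9e-07), Gbp2 by 2.96 and Igtp by 2.43. Of the 31 antiviral effectors 24 rose and 2 fell (24 and 2 adjusted over the list alone, median 1.03), and of the 8 GTPases 6 rose (7, median 2.23). Of 13 MHC class I members 9 rose (10, median 0.56), including the class I heavy chain H2-K1 up by 1.11 and Psmb9 by 0.99. Camera gave adjusted p of 4.12e-11 for antiviral effectors, 1.59e-07 for GTPases and 0.000774 for MHC class I. With an estimated correlation these were adjusted p = 0.143, 0.202 and 0.363. Irf7 rose by 1.63, Irf9 by 1.49 and the cytokine Il6 by 1.29, while Socs3 fell by 0.74.

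Most tested genes of cholesterol and fatty acid synthesis had lower signals with AMN107 in the absence of interferon. Idi1, the isopentenyl diphosphate isomerase of the mevalonate pathway, fell by 2.27, from a signal of 1336 ± 56.2 to 270.6 ± 29.4 (SD, n = 2; SE 0.11, limma adjusted p = 6.37e-07). Hmgcs1, which makes HMG-CoA, fell by 1.66 (3 other probe sets -1.85, -1.79 and -0.63). The desaturase Scd2 fell by 1.65, while its 2 other, dimmer probe sets gave -0.14 and -0.52. Of the 20 members of cholesterol and fatty acid synthesis, 16 were lower (18 adjusted over the list alone, median -0.95, camera adjusted p = 6.08e-13, adjusted p = 0.143 with an estimated correlation). Lysosome and autophagy rose in 13 of 18 (14 over the list alone, median 0.51, adjusted p = 0.000159, adjusted p = 0.207 with an estimated correlation), with the autophagy receptor Sqstm1 up by 1.68 and the proton pump subunit Atp6v0d1 by 1.57. ER stress and amino acid response rose in 13 of 21 and fell in 1 (14 and 1 over the list alone, median 0.45, adjusted p = 0.000159, adjusted p = 0.202 with an estimated correlation), with Ddit3, a stress transcription factor, up by 1.13. Immediate early and SRF targets rose in 13 of 24 and fell in 3 (16 and 4 over the list alone, median 0.57, adjusted p = 0.00617, adjusted p = 0.207 with an estimated correlation, and 0.0544 with the filter at the 75th percentile), with Ankrd1 up by 1.68 and Egr1 by 1.02.

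Col3a1, a fibrillar collagen, fell by 2.31 with AMN107 alone (SE 0.14, limma adjusted p = 3.36e-06; another, dimmer probe set -1.14) and S100a4 by 1.22. The list of ABL and other nilotinib targets also holds ABL partners such as Crk and Abi1. In it, the growth factor receptor Pdgfrb fell by 1.29 (SE 0.17, limma adjusted p = 0.000414) and the collagen receptor Ddr1 by 0.96. Of the 16 members of that list 5 fell and 1 rose (5 and 1 adjusted over the list alone, median -0.17, camera adjusted p = 0.0694). Another, dimmer probe set of Pdgfrb gave -0.04. Abl2 gave 0.05 (SE 0.09, adjusted p = 0.705) and Pdgfra -0.16 (SE 0.14, adjusted p = 0.396). The 2 other Abl2 probe sets gave -0.02 and 1.43. The glycosyltransferase B4galnt2, from 39.2 ± 4.91 to 346.8 ± 0.04 (SD, n = 2), rose by 2.90 (2 other, dimmer probe sets 0.71 and 0.89), and Cth, an enzyme of cysteine synthesis, by 2.32.

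At least a 2-fold effect of AMN107 without interferon passed for 300 genes (264 higher and 36 lower), and leaving out any 1 array gave 266 to 355. Among all changes 4237 genes passed (2529 higher and 1708 lower), 1683 and 2640 with quantile normalization and 2991 and 1207 with median centring. The total was 1969 and 2705 without DMSO replicates 1 and 2, 2367 and 2067 without AMN107 replicates 1 and 2, 6711 and 6714 without IFNa replicates 1 and 2, and 6713 without both. The LysX spike separated the AMN107 from the DMSO arrays.

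**Figure D2:**
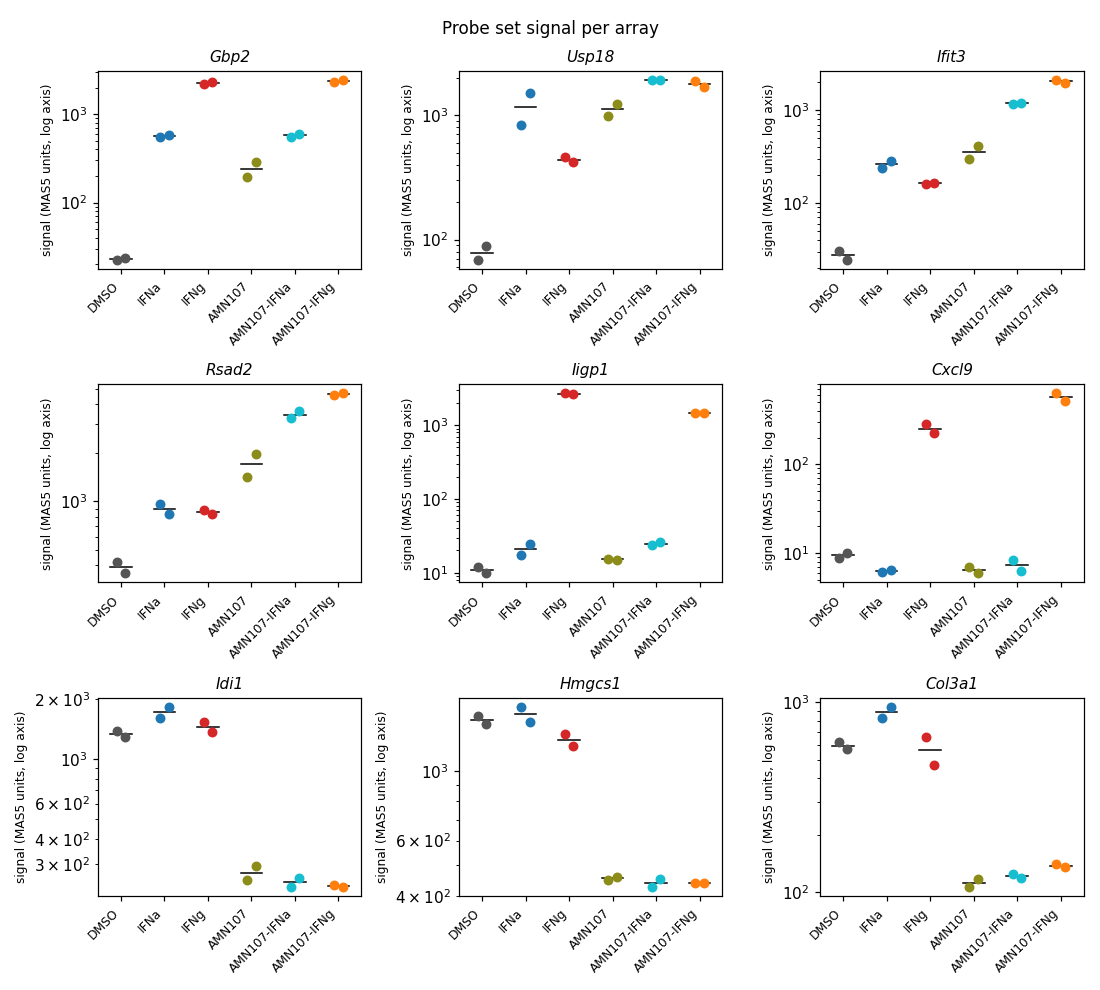
Probe set signal in MAS5 units on a log axis for 9 genes by group, with points for the 2 arrays and lines for their mean. AMN107 alone took Usp18 from 78.5 to 1109 and Idi1 from 1336 to 270.6, while Iigp1 had a mean of 15.1 with AMN107 and 2691 with IFNg.

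With IFNg present, where the LysX ranges of the groups overlapped but the BioB and GAPDH ranges did not, antiviral genes were again higher with AMN107. Ifit3 rose 11.9-fold, from 164 ± 3.18 to 2039 ± 122 (SD, n = 2; log2 3.57, SE 0.15, limma adjusted p = 4.71e-07). Rsad2, which makes an antiviral nucleotide, rose by 2.42, Ifit1 by 2.35 and Cmpk2 by 2.23. In all, 22 of 31 antiviral effectors rose (25 with 1 lower over the list alone, median 0.78, camera adjusted p = 1.82e-13, adjusted p = 0.0918 with an estimated correlation). The GTPases did not share this: 2 of 8 fell (2 over the list alone, median -0.04, camera adjusted p = 0.301), Iigp1 by 0.86 and Gbp6 by 0.57. Irf8 fell by 0.96 and the transporter subunit Tap2 by 0.68, while Nlrc5 rose by 0.75, Il6 by 1.73, Cxcl9 by 1.16 and Stat2 by 0.78. Of the cholesterol and fatty acid genes 16 of 20 were lower (18 over the list alone, median -1.12, camera adjusted p = 2.29e-20, adjusted p = 0.0567 with an estimated correlation), with Idi1 at -2.60, Scd2 at -1.94 (2 other probe sets -1.43 and -0.82) and Msmo1 at -1.78 (another, dimmer Msmo1 probe set 0.03). Cell cycle and DNA replication had 6 of 29 lower (7 over the list alone, median -0.19, adjusted p = 0.000116, adjusted p = 0.393 with an estimated correlation), including Cdc6, which loads the replicative helicase, at -0.67.

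B4galnt2 rose by 2.99 (2 other probe sets 0.58 and 1.17) and Aldh1l2, a mitochondrial folate enzyme, by 2.45 with AMN107 in the presence of IFNg. Abl2 rose by 0.53 (SE 0.09, limma adjusted p = 0.00303) and Pdgfrb gave -0.40 (SE 0.17, adjusted p = 0.128). At least a 2-fold effect passed for 171 genes (132 higher and 39 lower), and leaving out any 1 array gave 161 to 177. Among all changes 2334 passed (1632 higher and 702 lower), 1225 and 984 with quantile normalization. The total was 1236 and 1157 without IFNg replicates 1 and 2, 921 and 1187 without AMN107-IFNg replicates 1 and 2, 4927 without either IFNa array, and 4928 without both.

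With IFNa present, B4galnt2 was higher with AMN107 by 2.83 (SE 0.14, limma adjusted p = 1.36e-06), Ifit3 by 2.16, from 261.6 ± 29.3 to 1193 ± 19.6 (SD, n = 2), and Rsad2 by 1.94. The 2 other B4galnt2 probe sets gave 0.86 and 1.25. Antiviral effectors rose in 15 of 31 and fell in 2 (15 and 2 adjusted over the list alone, median 0.34, camera adjusted p = 3.24e-05, adjusted p = 0.322 with an estimated correlation). Idi1 fell by 2.78, Col3a1 by 2.78, Scd2 by 1.87 and Pdgfrb by 1.43 (SE 0.17, adjusted p = 0.000326). Other, dimmer probe sets gave -1.90 for Col3a1, -0.33 and -0.46 for Scd2 and -0.31 for Pdgfrb. In the list of ABL and other nilotinib targets 5 of 16 members fell (7 over the list alone, median -0.18, camera adjusted p = 0.0164, adjusted p = 0.322 with an estimated correlation). In cholesterol and fatty acid synthesis 16 of 20 members were lower (17 over the list alone, median -1.24, camera adjusted p = 8.59e-15, adjusted p = 0.125 with an estimated correlation). Stat2 rose by 1.11 (SE 0.15, adjusted p = 0.000602), while Irf1 gave 0.13 (SE 0.12, adjusted p = 0.446).

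At least a 2-fold effect of AMN107 with IFNa passed for 231 genes (137 higher and 94 lower), and 628 without IFNa replicate 1. Among all changes 3173 passed (1375 higher and 1798 lower). The total was 6187 without IFNa replicate 1, 1333 and 1773 without AMN107-IFNa replicates 1 and 2, 98 in a fit of these 2 groups alone and 988 with array weights. The LysX spike separated the AMN107-IFNa from the IFNa arrays.

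Averaged over the 3 interferon states, Ifit3 was higher with AMN107 by 3.01 (SE 0.08, limma adjusted p = 4.68e-09), B4galnt2 by 2.91 (2 other probe sets 0.72 and 1.104), Rsad2 by 2.15 and Usp18 by 2.15. Lower were Idi1 (log2 -2.55, SE 0.06, adjusted p = 2.42e-09), Col3a1 (-2.34, another, dimmer probe set -1.365) and Hmgcs1 (-1.65). Cholesterol and fatty acid synthesis had 18 of 20 members lower (18 adjusted over the list alone, median -1.16, camera adjusted p = 3.21e-14, adjusted p = 0.137 with an estimated correlation). Lysosome and autophagy had 14 of 18 higher and 3 lower (15 and 3, median 0.35, adjusted p = 0.00205, adjusted p = 0.314 with an estimated correlation). Cell cycle and DNA replication had 16 of 29 lower and 4 higher (16 and 4, median -0.25, camera adjusted p = 0.00956, adjusted p = 0.348 with an estimated correlation), with Ccne2 at -0.78, Cdc6 at -0.70 and the nucleotide enzyme Rrm2 at -0.66. Most of this difference came from the states with interferon. The mean log2 signal of this list was 9.45 with DMSO and 9.38 with AMN107. It was 9.65 with IFNa (9.54 and 9.76 on replicates 1 and 2) and 9.35 with AMN107-IFNa. With IFNg it was 9.58 and with AMN107-IFNg 9.33. Extracellular matrix had 8 of 21 lower and 3 higher (11 and 4 over the list alone; camera adjusted p = 0.109), and hypoxia and glycolysis 7 of 18 lower and 1 higher (7 and 1; 0.0749) with Egln3, an oxygen sensor, at -1.02. Chemokines and cytokines had 8 of 19 higher and 1 lower (8 and 1; 0.0869) with Il6 at 1.43. Abl1 gave -0.15 (SE 0.05, adjusted p = 0.0191), a call lost without DMSO replicate 2 (adjusted p = 0.053), AMN107 replicate 1 (0.064) or AMN107-IFNg replicate 1 (0.0575), and Pdgfra -0.05 (SE 0.08, adjusted p = 0.657).

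Members of several lists moved in both directions in the average over states. p53 targets had 3 of 14 higher and 6 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.374), with the growth arrest gene Gadd45a at 1.17 and Ccng1 at -1.07. Oxidative and xenobiotic stress had 5 of 12 higher and 4 lower (5 and 4; 0.936), with the haem oxygenase Hmox1 at 0.93 and Cyp1b1 at -1.12. NF-kappaB targets had 4 of 14 higher and 5 lower (4 and 5; 0.475), with the inhibitor Nfkbie at -0.74. Cell death and checkpoint ligands had 6 of 14 higher and 2 lower (6 and 2; 0.109), with Daxx at 0.96. Interferon signalling had 7 of 17 higher and 3 lower (8 and 3; 0.219), and interferon feedback inhibitors 4 of 10 higher and 4 lower (4 and 4; 0.938, median -0.01 but mean 0.21). Of 2 tested members of MHC class II presentation, H2-Eb1 gave -0.19 and was the 1 lower (1 over the list alone; 0.265).

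Among the cell type markers in the same average, fibroblast markers had 2 of 8 higher and 4 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.219), with S100a4 at -1.26 and Pdgfrb, which is also in the nilotinib target list, at -1.04 (another probe set -0.16). Macrophage and leukocyte markers had 1 of 6 higher and 1 lower (over the list alone, 1 higher; 0.979, median -0.03 but mean 0.09), with the Fc receptor Fcgr3 at 0.77. Epithelial markers had 2 of 3 lower (2; 0.0629), the keratin Krt8 at -0.67 and Epcam at -0.34, and endothelial markers 1 of 2 lower (1; 0.37). Muscle markers had 1 of 7 higher and 2 lower (1 and 2; 0.843, median 0.04 but mean -0.07), with Tnnt2 at -0.65. Fat and cartilage markers had 2 of 3 higher and 1 lower (2 and 1; 0.209), the lipid carrier Fabp4 at 0.72 and the transcription factor Sox9 at 0.50. Neural markers had 2 of 5 higher (2 over the list alone, camera adjusted p = 0.252), with Tubb3 at 1.03. Fibroblast markers had group means of 8.035 to 8.48 (log2). The other marker lists had 5.24 to 6.44, under the array medians of the tested genes, 6.88 to 7.10. Shifts in these dim lists do not establish a change in cell types.

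At least a 2-fold averaged effect of AMN107 passed for 166 genes (123 higher and 43 lower), and leaving out any 1 array gave 160 to 184. Among all changes 5857 genes passed (3174 higher and 2683 lower), 2555 and 3508 with quantile normalization. The LysX spike separated the groups in 2 of the 3 states averaged, and the GAPDH ratio in all 3. Between the states without interferon and with IFNg, which share no array, AMN107 effects correlated at 0.747 across 12192 genes, which are not independent replicates. Between them 81 genes rose at least 2-fold in both and 22 fell, against 2.86 and 0.115 if the calls were independent. Both tests use the same spread per gene, so the calls are not independent and these expected counts are too low a mark.

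**Figure D3:**
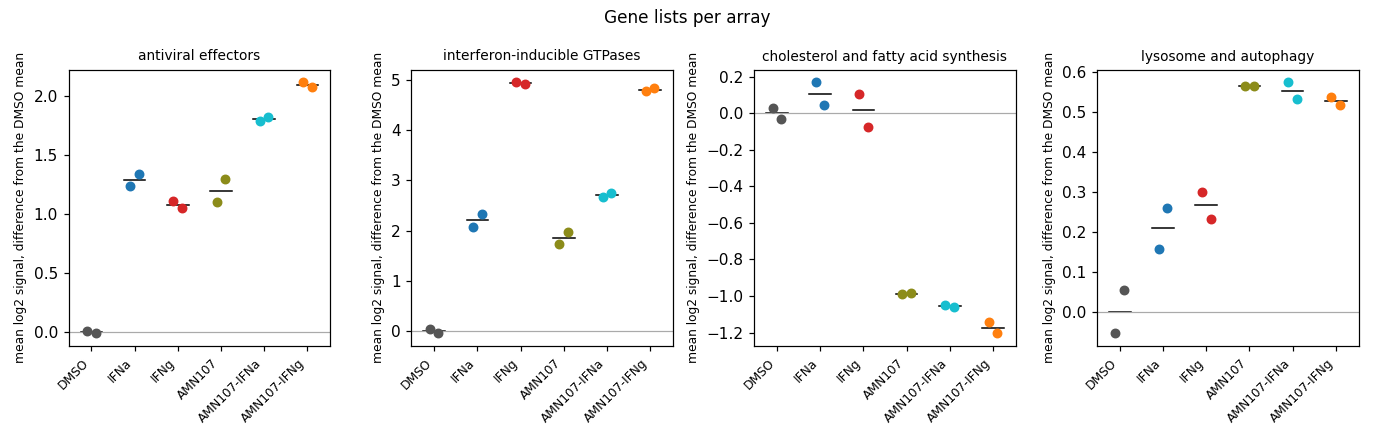
Mean log2 signal of 4 gene lists per array as the difference from the DMSO mean, by group, with points for the 2 arrays and lines for their mean. The cholesterol and fatty acid synthesis list lies lower on all 6 AMN107 arrays, with 16 of 20 members called lower in each interferon state.

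Under AMN107, the response to IFNa was small. Ifit3 gave the largest rise, 1.75, from a signal of 353.9 ± 80.1 to 1193 ± 19.6 (SD, n = 2; SE 0.15, limma adjusted p = 0.00228), followed by the GTPase Ifi47 at 1.35 (lost in 7 of 12 fits with 1 array left out), Trim30a at 1.29 and Gbp2 at 1.24. In antiviral effectors 8 of 31 rose (22 adjusted over the list alone, median 0.59), in GTPases 5 of 8 (8, median 0.89), in MHC class I presentation 1 of 13, Tap1 (8, median 0.31), and in sensors 2 of 13 (9, median 0.36). Camera gave adjusted p of 1.18e-67, 1.65e-40, 9.18e-24 and 6.75e-20 for these lists, and adjusted p = 0.00242, 0.00441, 0.0119 and 0.00594 with an estimated correlation. Irf9 gave 0.19 (SE 0.17, adjusted p = 1) and Irf7 0.75 (SE 0.24, adjusted p = 0.85).

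The 31 genes past the test in the IFNa response under AMN107 were all higher, 8 of them by at least 2-fold. Without AMN107-IFNa replicate 1 or 2 limma called 0 genes (351 genes had an unadjusted p under 0.05 with all arrays), without AMN107 replicate 1 it called 1, without either IFNg or either AMN107-IFNg array 17, and without either IFNa array or both 125 (116 higher and 9 lower). Ifit3 had an adjusted p of 0.0698 and 0.082 without AMN107-IFNa replicates 1 and 2. Gbp2 had 0.0572, 0.115 and 0.197 without AMN107 replicate 1 and these 2 arrays, and Trim30a 0.181, 0.115 and 0.197.

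The test of the difference between IFNa responses with and without AMN107 found smaller responses under AMN107. The response of Gbp2 differed by -2.95 (log2; SE 0.20, limma adjusted p = 0.000192), that of Mndal by -2.48, of Gbp3 by -2.36, of Gbp7 by -2.09 and of Xaf1 by -1.95. GTPases had 5 of 8 lower (6 adjusted over the list alone, median -1.22, camera adjusted p = 9.21e-07, adjusted p = 0.302 with an estimated correlation). Antiviral effectors had 8 of 31 lower (15 with 1 higher, median -0.49, adjusted p = 2.23e-06, adjusted p = 0.302 with an estimated correlation). Over the 46 genes that IFNa induced, the median response was 1.99 without and 0.77 with AMN107, the median difference was -1.19 (fry adjusted p = 0.000159). All 46 had a smaller response, 21 of them past the test. The IFNa arrays varied more than the others, which favours a more negative difference in genes chosen by their mean response. The median was -1.28 without IFNa replicate 1 and -1.15 without IFNa replicate 2. With AMN107 alone 42 of these 46 were higher than with DMSO (median 1.88), and with IFNa present their median AMN107 difference was 0.22. For the 8 genes induced at least 4-fold, the median difference was -2.42 (fry adjusted p = 5.28e-05).

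The difference between IFNa responses passed the test in 25 genes, all lower. The count was 11 and 14 without DMSO replicates 1 and 2, 5771 (2087 higher and 3684 lower) and 80 (1 and 79) without IFNa replicates 1 and 2, 13 without AMN107 replicate 2, 11 and 14 without AMN107-IFNa replicates 1 and 2, and 8 in a fit of the 4 groups alone. The median difference of all genes was -0.07, and 0.05 with quantile normalization.

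IFNg induced most of its strongest targets under AMN107 as well. Iigp1 rose by 5.96, from a signal of 15.1 ± 0.50 to 1476 ± 13.7 (SD, n = 2; SE 0.11, limma adjusted p = 6.06e-10), Cxcl9 by 5.27, Ifi47 by 3.97, Gbp2 by 3.27, Nlrc5 by 2.83, Cd274 by 2.55, Irf1 by 2.50 and Stat2 by 1.33. All 8 GTPases rose (8 adjusted over the list alone, median 2.68), 19 of 31 antiviral effectors (25, median 0.82), 9 of 13 in MHC class I presentation (11, median 1.09), 9 of 19 chemokines and cytokines (11, median 0.54) and 8 of 14 cell death and checkpoint ligands (9, median 0.60), with the inflammatory caspase Casp4 up by 2.52. Camera gave adjusted p of 6.24e-42, 2.42e-41, 1.04e-27, 1.09e-19 and 1.87e-19, and adjusted p = 0.00338, 0.00338, 0.00671, 0.00338 and 0.00178 with an estimated correlation. Irf7 gave 0.78 (SE 0.24, adjusted p = 0.185) and Irf9 0.34 (SE 0.17, adjusted p = 0.616). Neural markers had 1 of 5 higher, Tubb3 by 2.81 (1 over the list alone), with a median of -0.04 but a mean of 0.58 and a camera adjusted p of 0.039 (adjusted p = 0.137 with an estimated correlation). That call was lost without AMN107-IFNg replicate 1 (adjusted p = 0.0778) and, at 0.05 to 0.06, without AMN107 replicate 1, either IFNg array or either AMN107-IFNa array.

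The 108 genes past the test with at least a 2-fold response to IFNg under AMN107 were all higher, and leaving out any 1 array gave 95 to 119. Among all changes 316 passed (303 higher and 13 lower). The total was 150 and 180 without AMN107 replicates 1 and 2, 153 and 159 without AMN107-IFNg replicates 1 and 2, 871 and 873 without IFNa replicates 1 and 2, and 874 without both (586 higher and 288 lower). It was 1330 in a fit of these 2 groups alone (750 and 580).

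The IFNg responses with and without AMN107 differed most in the GTPases. All 8 had a smaller response under AMN107 (8 adjusted over the list alone, median -2.15, camera adjusted p = 8.69e-24, adjusted p = 0.0532 with an estimated correlation), Gbp2 by -2.89 (SE 0.20, limma adjusted p = 0.000215), Igtp by -2.46, Gbp7 by -2.46 and Irgm2 by -2.23. The end level of Gbp2 was close: it reached 2255 ± 43.3 with IFNg and 2372 ± 113 with AMN107 and IFNg (SD, n = 2), against 23.1 and 242.9 without IFNg, whereas Iigp1 reached 2691 and 1476 and was lower with AMN107, as was Gbp6. MHC class I had 2 of 13 lower (7 over the list alone, median -0.47, adjusted p = 1.7e-06, adjusted p = 0.252 with an estimated correlation). Lysosome and autophagy had 2 of 18 lower (3, median -0.22, adjusted p = 2.69e-05, adjusted p = 0.252 with an estimated correlation). Antiviral effectors had 5 of 31 lower, among them Xaf1 by -1.65, and 1 higher (8 and 4 over the list alone, median 0.02 but mean -0.18, adjusted p = 0.209). The Cxcl9 response was larger under AMN107 by 1.42 (SE 0.18, adjusted p = 0.00798), a call lost without DMSO replicate 1 (adjusted p = 0.0539) or AMN107 replicate 2 (0.0659).

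Over the 116 genes that IFNg induced, the median response was 1.65 without and 1.47 with AMN107 and the median difference was -0.27 (fry adjusted p = 0.016). For the 33 genes induced at least 4-fold, the medians were 3.23 and 2.52 and the median difference was -0.74 (fry adjusted p = 0.000373). Of the 116 genes 84 had a smaller response, 23 were past the test as lower and 5 as higher. With AMN107 alone 65 of these 116 were higher than with DMSO (median 0.59) and 4 lower. The adjusted p was 0.0529 without DMSO replicate 1 and 0.0629 without AMN107-IFNg replicate 2, where the median differences were -0.25 and -0.25. The difference passed the test in 125 genes (109 lower and 16 higher), 11 and 45 without DMSO replicates 1 and 2, 17 and 22 without IFNg replicates 1 and 2, and 21 and 13 without AMN107 replicates 1 and 2. It was 58 and 60 without AMN107-IFNa replicates 1 and 2, 18 and 15 without AMN107-IFNg replicates 1 and 2, 1577 and 1576 without IFNa replicates 1 and 2, and 1579 without both (441 higher and 1138 lower).

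**Figure D4:**
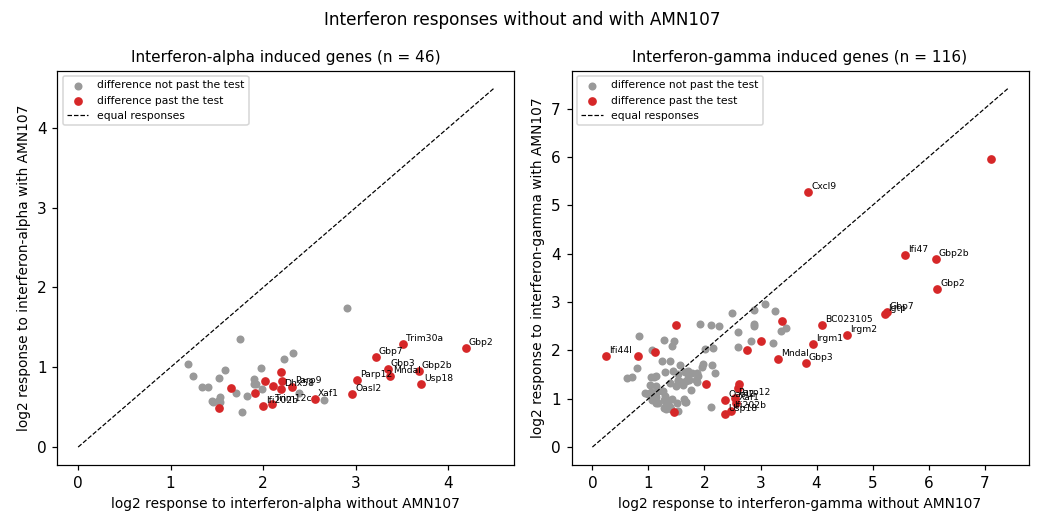
Log2 response of the 46 genes induced by IFNa and the 116 induced by IFNg, without AMN107 on the x axis and with AMN107 on the y axis; each point is a gene, in red where the difference passed limma's test, and the dashed line marks equal responses. All 46 points for IFNa lie below the line, and Cxcl9 lies above it for IFNg.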

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

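Of the tests in this part, the distance of IFNa replicate 2 to the other groups and the count over other splits of the arrays were set before their results were seen, and all other tests of technical explanations were chosen after. The interactions were planned.

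The responses to interferon differed between cells without and with AMN107 by a test of the difference. For IFNa the median difference over 46 induced genes was -1.187, and the largest called single-gene differences were Gbp2 -2.95, Usp18 -2.915, Gbp2b -2.73, Mndal -2.48, Gbp3 -2.365 and Oasl2 -2.30 (Oasl2 adjusted p = 0.0587 without DMSO replicate 1 and 0.056 without AMN107-IFNa replicate 1). For IFNg the median difference was -0.273 over 116 genes and -0.741 over the 33 induced at least 4-fold, with Gbp2 at -2.89, Igtp at -2.46, Gbp7 at -2.46, Gbp2b at -2.24, Irgm2 at -2.225 and Gbp3 at -2.07.

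Larger IFNg responses under AMN107 were called for Ifi44l at 1.64, Mx1 at 1.53, Cxcl9 at 1.42, Gm11772 at 1.12, Crem at 1.07, Casp4 at 1.03, Marcks at 0.962 (6 other probe sets 0.07 to 0.45), Daxx at 0.952, Trafd1 at 0.844, Endod1 at 0.741 (other probe sets 0.29, -0.97 and -0.15), Clic5 at 0.68 and Tmsb4x at 0.68. Each of these 12 calls was lost without DMSO replicate 1, where the adjusted p was 0.0502 for Ifi44l, 0.0684 for Mx1 and 0.0539 for Cxcl9. Signals outside the comparisons also differed from the controls: the mean ratio of 5' to 3' actin signal was 0.793 on the IFNg arrays, 0.818 on the AMN107, 0.814 on the AMN107-IFNa and 0.803 on the AMN107-IFNg arrays, above both DMSO arrays (0.676 and 0.712).

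IFNa replicate 2 stood apart from replicate 1. Its GAPDH ratio of 5' to 3' signal was 0.0252, far below the range of the other 11 arrays, as degraded RNA or short cDNA would give. RNA of another group is argued against: over 622 genes that separate the other groups, its root mean square log2 distance was 0.54 to IFNa replicate 1 and 0.863 to 1.19 to the other 5 groups. No biological explanation was tested, since the 2 arrays carry the same treatment.

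Genes that interferons induce, such as Usp18 and Ifit3, were higher with AMN107 alone. Material from the IFNa or IFNg cultures mixed into the AMN107 arrays is argued against as the whole cause: of 44 such genes, 11 lay above both IFNa arrays and 14 above both IFNg arrays on both AMN107 arrays, and the share of IFNg material that 19 strongly induced genes would need ran from -1.4% (Irf8) to 48.1% (Mndal). Material from the AMN107-IFNa or AMN107-IFNg cultures was not tested. For the antiviral effectors, a preparation difference marked by the LysX spike is argued against as the only source by their median rise of 0.781 with IFNg, where the spike ranges overlapped (fry adjusted p = 3.11e-05, but camera adjusted p = 0.0918 with an estimated correlation); for the GTPases it cannot be told apart from AMN107, since their median there was -0.0417 and IFNg itself raised all 8. A preparation difference marked by the GAPDH ratio cannot be told apart from AMN107 in any state, for these genes or others, since the ratio was at least 1.12 on the 6 AMN107 arrays and at most 1.1 on the others. Type I interferon carried over into, or made in, the AMN107 cultures cannot be told apart from an effect of AMN107 inside the cells: the AMN107 effect as a share of each gene's own IFNa response had a median of 79.2% over the 46 induced genes, the 35 of the 116 genes induced by IFNg that did not pass the test for IFNa had a median of 0.06, no interferon level was measured, and an effect of the kinase inhibitor stays open, untested.

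Many small differences came with AMN107: without interferon, a preparation difference cannot be told apart from AMN107, since the mean spike signal was 62.9 on the DMSO arrays and 38.3 on the AMN107 arrays and follows the groups. A difference that LysX marks is argued against as the only source with IFNg, where the LysX ranges overlapped and 2334 genes passed (921 to 4927 with 1 array left out), but BioB (134.1 and 140.5 against 171.7 and 178.9) and the GAPDH ratio (lowest on AMN107 arrays 1.12) separated these arrays, so a preparation difference that they mark cannot be told apart from AMN107. The 2% trimmed mean of the arrays also separated these groups, 100.4 and 101.2 with DMSO against 109.7 and 110.1 with AMN107. With IFNg it was 106.2 and 104.9 against 110.1 and 110.8 with AMN107-IFNg. Quantile normalization, which gives all arrays 1 distribution, moved the calls without interferon from mostly higher to mostly lower. Their direction thus depended on the scaling. After the trend on 5' signal loss was removed, 6572 genes passed without interferon, against 6713 in the same fit, without both IFNa arrays, before. This does not decide on loss of 5' signal, since the trend was taken from the difference between the 2 IFNa arrays. The arrays of this fit had GAPDH ratios of 1.074 to 1.16, so they had little such loss to remove. For the average over 3 states, 1 of 100 splits drawn of 108 (the real one, with 5857 genes) gave as many genes, and the highest other split gave 3433. Most other splits put arrays with and without AMN107 into the same group, which widens the spread and lowers their counts. The splits therefore cannot decide on chance.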

How the results depend on the processing

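Array weights, the fit without both IFNa arrays and the removal of the trend on 5' signal loss were chosen after seeing the data, and the other alternatives were planned. Counts are of genes with limma adjusted p under 0.05 unless stated. The cause was not tested except where the construction of an alternative shows it.

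A minimum of 2-fold, which can only lower a count, left 77 for the IFNa response, 156 for IFNg, 8 and 108 for IFNa and IFNg under AMN107, 300 for AMN107 without interferon, 231 with IFNa, 171 with IFNg, 166 averaged, 41 for the interaction with IFNg and 86 for IFNg against IFNa. Every probe set on its own, which tests more features, gave 2189 for IFNg, 8056, 5879 and 3741 for AMN107 without interferon, with IFNa and with IFNg, 11165 averaged, 335 for the interaction with IFNg and 3442 for IFNg against IFNa. Quantile normalization gave 1047 for IFNa, 82 for the interaction with IFNg and 1380 for IFNg against IFNa, median centring 3291 for IFNa and 20 for IFNa under AMN107, and the filter at the 75th percentile 1129 for IFNa, where fewer genes were tested; the cause was not tested for the scalings.

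A fit on only the groups compared gave 35 for IFNa, 3031 for IFNg, 122 and 1330 for IFNa and IFNg under AMN107, 6760, 98 and 4667 for AMN107 without interferon, with IFNa and with IFNg, 8 and 1564 for the interactions with IFNa and IFNg, and 36 for IFNg against IFNa. Array weights (0.149 for both IFNa arrays, 1.11 to 1.85 for the others) gave 84, 3049, 139, 1125, 6910, 988 and 4711 for the first 7 of these in the same order, 1462 for the interaction with IFNg and 110 for IFNg against IFNa. Without both IFNa arrays the counts were 3728 for IFNg, 125 and 874 under AMN107, 6713 and 4928 for AMN107 without interferon and with IFNg, and 1579 for the interaction with IFNg. With the 5' trend removed they were 3432, 124, 885, 6572, 4963 and 1460. For the removal of the trend the cause was not tested. Leaving out the IFNa arrays does not change the means of the other groups, so there only the spread behind the tests changed. The IFNa arrays varied more (replicate difference SD 0.401 against 0.119 to 0.144) and are part of the shared spread in the main fit. The 2 arrays of a group get equal weights by construction, so 0.149 does not mark either IFNa array as the poorer. In the fit on only the groups compared, the 6 counts listed that use no IFNa array rose and the 4 that use them fell.

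Leaving out each array in turn gave 100 to 7142 for IFNa, 275 to 3733 for IFNg, 0 to 125 for IFNa under AMN107 (351 genes had an unadjusted p under 0.05 in limma with all arrays), 150 to 873 for IFNg under AMN107, 1969 to 6714, 1333 to 6187 and 921 to 4927 for AMN107 without interferon, with IFNa and with IFNg, 4827 to 7617 averaged, 11 to 5771 and 11 to 1577 for the interactions with IFNa and IFNg, and 254 to 6371 for IFNg against IFNa. The lone array of a group was assumed to vary like the other groups. The averaged AMN107 count moved by less than 1.5 times in these fits. The replicate number as a block gave 2269, 1064, 29, 312, 4289, 3211, 2292, 5857, 25, 110 and 2210, in the order of this paragraph.

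The median difference between IFNa responses over induced genes ran from -1.40 to -1.01 and past the test when each array was left out. For IFNg it ran from -0.37 to -0.19, with a fry adjusted p of 0.0529 without DMSO replicate 1 and 0.0629 without AMN107-IFNg replicate 2 (-0.25 in both); the cause was not tested.

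Over the alternatives set in advance, list results kept direction and side of the threshold in 1670 cases. They were no longer past it in 122 and reversed in 4. Only lists past camera in the main fit were followed, so none could pass newly. The estimated correlation was 1 of these alternatives, and many of the 122 losses came there. The other alternatives kept the preset correlation of 0.01. Gene results kept theirs in 18524 cases, lost the threshold in 1853 and reversed in 1, and 159 passed only in the alternative. All 4 list reversals were of neural markers in the IFNg response under AMN107, whose median of -0.0422 became 1.55 with the filter at the 75th percentile, 0.0106 without AMN107 replicate 2, and 0.0227 and 0.043 without AMN107-IFNg replicates 1 and 2. The gene was Irf7 in IFNg against IFNa, which went from -0.09 to 0.377 without IFNa replicate 1 and to -0.559 without IFNa replicate 2. The cause was not tested. Under the added alternatives lists kept theirs in 195 cases and lost the threshold in 5, and genes in 2014 and 143, with 99 past it only there.

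Array medians were 20.6 to 22.7, and signals near the added 8.66 have damped log2 differences, so genes that start dim, such as Iigp1 at 10.9, have responses that are lower than their ratio of signals.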
